A study of Homo sapiens with 4 samples.

How the data were processed

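Total RNA from SUIT2 cells, a human cell line, was hybridised to 4 single-colour whole-transcript arrays with biotin label. Per the labels' protocols, RNA was extracted with Trizol and labelled as whole-transcript sense targets. The labels put 2 arrays in the control group (phosphate-buffered saline) and 2 in the fb-PMT group (30 µM), both after 24 h. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

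The deposited values are log2 probe set values made with RMA (background correction, normalization between arrays and a summary per probe set) in Transcriptome Analysis Console 4.0.1.36, per the submitters' processing notes. The RMA variant and the genome build are not given in the sources used here, so no coordinates are printed. Scanner files and detection calls were not used here. RMA shrinks differences of dim probe sets, and normalization between arrays removes any shift shared by most genes. The deposited table held 24351 probe sets. The 2903 control probe sets were left out and 21448 transcript clusters were tested. A transcript cluster is a probe set that summarises one locus. The platform annotation gave 1 gene symbol for 17709 of them, several for 0, and none for 3739, which are unnamed here. All 17709 Entrez identifiers matched the RefSeq gene table, and 0 symbols needed an update.

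The medians of the 4 arrays over the transcript clusters were 6.27 to 6.28. Their number limits the precision: the median standard error of a log2 difference was 0.175. The array's negative control probe sets served as background. Their 95th percentile was 7.38 and 7.22 on the control arrays and 7.15 and 7.29 on the fb-PMT arrays. A gene under it on both arrays of a group is called below the negative controls. Against such a group only a lower bound of the fold is given, computed from that percentile ("at least"), and no fold is given where both groups are below it. In all, 11820 transcript clusters were below it on all 4 arrays.

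Each transcript cluster was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without an intensity trend), fb-PMT minus control, with no covariate. The p-values are two-sided, and adjusted p-values are Benjamini-Hochberg over the 21448 transcript clusters with a threshold of 0.05. The moderated variance had 2 residual and 3.72 prior degrees of freedom. Exchanging labels among 4 arrays gives too few arrangements for a permutation test per gene to reach this threshold.

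Before the data were examined, 40 gene lists with 1147 genes were written from textbook knowledge. Of these genes 1005 were measured, and 39 lists had at least 5 measured members. The 13 mitochondrially encoded genes had no named transcript cluster and were not analysed here by name. Unnamed transcript clusters with identifiers that begin with TC0M were fitted with the others. Lists were tested with camera in limma on the genes with a symbol, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 39 lists. Genes of a list were also counted with p-values adjusted over the list alone.

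The genes named were set by a rule written before the data were examined. It takes the 12 largest rises and the 12 largest falls among transcript clusters with 1 symbol that passed and whose fb-PMT arrays both lay beyond both control arrays. Where fewer than 12 passed, the smallest unadjusted p filled the places. From each list it takes up to 4 passing members (the 2 largest rises and the 2 largest falls), or, where none passed, the 2 with the largest difference. ITGAV, ITGB3, THRA, THRB, KRT8, KRT18, KRT19, EPCAM, GFAP, OLIG2, COL1A1 and PTPRC are always given. Other genes named, those of the closing section included, were chosen after their values were seen.

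The fit was tested on simulated data in 20 runs with 200 changed transcript clusters each. Means were the real ones, while variances were drawn from limma's fitted prior without regard to intensity, so the recovery rates hold for that model. It recovered 11.7% of 2-fold changes, 88.2% of 4-fold, 97.4% of 8-fold and 99.2% of 16-fold changes, with 8.2 false calls per run. A simulated list shifted by -0.25 passed camera in 20 of 20 runs with the preset correlation and in 0 of 20 with an estimated correlation. With the preset, 0 unshifted lists were called. The simulated genes varied independently of each other, so these runs cannot show how the preset correlation performs for real genes that vary together.

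The alternatives were the replicate number as a block, an intensity trend with and without robust variances, leaving out the lowest 30% of transcript clusters, testing only those with 1 symbol, renewed quantile normalization, centring on medians, array weights, leaving out each array, other thresholds, camera with an estimated correlation, fry, and the mean over transcript clusters of one symbol. A filter that keeps transcript clusters above the negative controls on at least 2 arrays was added after the data were seen.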

Results

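Transcript levels were measured in SUIT2 cells exposed for 24 h to fb-PMT at 30 µM (n = 2 arrays) or to phosphate-buffered saline (n = 2 arrays). SUIT-2 is known as a pancreatic ductal adenocarcinoma line, although the labels call these cells glioblastoma. fb-PMT is a derivative of tetraiodothyroacetic acid, a thyroid hormone analog, linked to polyethylene glycol and carrying a fluorobenzyl group. It was designed to block the thyroid hormone receptor site on integrin αvβ3. The stated question was how the drug alters transcription of genes that mitochondria of cancer cells need. Replicate arrays correlated across transcript clusters with r = 0.995 in the control group and 0.996 in the fb-PMT group, and arrays of different groups with 0.992 to 0.994.

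Among transcript clusters with a gene symbol, 20 rose with fb-PMT, led in measured difference by OLFM1, which encodes a secreted olfactomedin glycoprotein. OLFM1 went from a log2 value of 3.52, below the negative controls, to 9.05 (at least 3.36-fold higher, adjusted p = 0.0014). ABCG2, a drug efflux transporter, rose 11.2-fold (log2 difference 3.49, SE 0.15, adjusted p = 0.00669). IRF1, a transcription factor of the interferon response, rose 6.57-fold (SE 0.17, adjusted p = 0.0179). The death ligand gene TNFSF10 (TRAIL) rose 4.84-fold and the interferon-inducible GTPase gene GBP4 at least 4.45-fold (both with adjusted p = 0.0179). LGALS9, which encodes the glycan-binding protein galectin-9, rose 8.12-fold.

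The other genes among the 12 largest rises by measured difference were CPM, TNFRSF9, GRAMD1C, LGALS9C, PLAAT4 and PDZK1. CPM encodes the membrane enzyme carboxypeptidase M and rose at least 3.93-fold (adjusted p = 0.0179). TNFRSF9, the costimulatory receptor 4-1BB, rose at least 3.01-fold (adjusted p = 0.0479), and PDZK1, a scaffold of membrane transporters, at least 3.15-fold (adjusted p = 0.0227). GRAMD1C, a member of a family of sterol transfer proteins, rose 6.34-fold and PLAAT4, a phospholipid-metabolising enzyme induced by retinoids, 4.78-fold. LGALS9C rose at least 2.32-fold. Genes below the negative controls in the control group have no settled rank, since only the bound of their rise is known. LGALS9, LGALS9B and LGALS9C are near-identical copies, so the array may not separate them and their individual values are uncertain.

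Named after their values were seen, the other 8 genes past the threshold were STC1, TC2N, SAT1, PSMB9, RNF4BP, LGALS9B, CLDN7 and CARD16. SAT1, which acetylates polyamines, rose 4.37-fold and STC1, a secreted glycoprotein hormone, 4.5-fold. PSMB9, a subunit of the immunoproteasome, rose 3.41-fold from a control log2 value of 12.11. CLDN7, a tight junction protein, rose 3.1-fold, and CARD16, which resembles part of CASP1 and is therefore uncertain, 3.05-fold. One further transcript cluster that rose, TC0900011565.hg.1, is unnamed here.

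No transcript cluster fell past the threshold. The 12 strongest falls, which did not pass, included ITGBL1, an integrin beta-like protein (2.52-fold lower, adjusted p = 0.0675), KRT80, a keratin (2.45-fold lower, adjusted p = 0.0756) and HAS2, a hyaluronan synthase (2.51-fold lower, adjusted p = 0.0765). The chromatin protein gene HMGA2 was 2.53-fold lower (adjusted p = 0.134), the amino acid transporter gene SLC38A4 2.26-fold lower, the sodium-proton exchanger gene SLC9A2 2.12-fold lower and the vesicle transport gene RAB27B 2.05-fold lower. AKR1B10, an aldo-keto reductase, was at least 1.83-fold lower (adjusted p = 0.123), ADAMTS15 at least 1.31-fold lower and MYH15 at least 1.17-fold lower. CIDEC, a lipid droplet protein with the smallest p among the falls (log2 difference -1.47, adjusted p = 0.0595), and STH (log2 difference -1.54, adjusted p = 0.115) were below the negative controls in both groups.

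**Figure D1:**
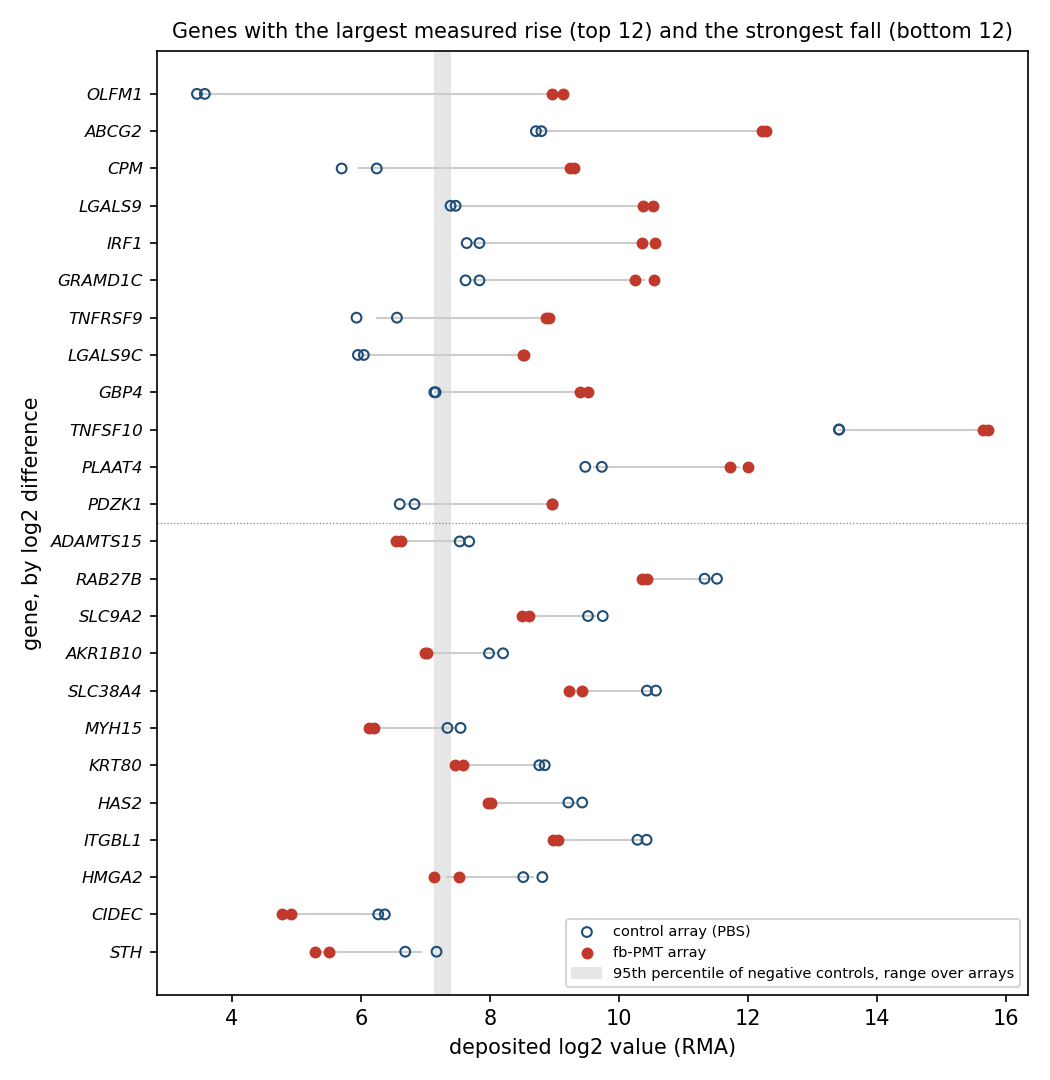
Deposited log2 values of the 12 genes with the largest rise by measured difference and the 12 with the strongest fall, per array (open circles, 2 control arrays; filled circles, 2 fb-PMT arrays; grey line, between group means; grey band, range over the arrays of the 95th percentile of negative controls). Both fb-PMT arrays lie beyond both control arrays for each gene, OLFM1 moves from below the band to above it, and the 12 falls did not pass the threshold.

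In limma's test, 21 transcript clusters were higher and 0 lower with fb-PMT, with folds of 3.05 and more as measured. At an unadjusted p under 0.05, 1222 were higher and 1177 lower, against 1072 expected in all by chance. With an intensity trend in the variance 293 were higher and 110 lower, all 12 of the strongest falls among them. The count of 21 became 9 without control replicate 1, 5 without control replicate 2, 1 without fb-PMT replicate 1 and 1 without fb-PMT replicate 2, and in the simulation 11.7% of 2-fold changes were recovered.

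For mitochondrial genes, the focus of the study, nuclear-encoded subunits of the respiratory chain and ATP synthase showed no difference past the test. Of 71 measured members of the oxidative phosphorylation list, 45 were higher and 26 lower with fb-PMT, by 0.047 on the log2 scale in the mean, and 0 passed, over all transcript clusters or adjusted over the list alone. Camera gave an adjusted p of 0.333. The differences between the 4 pairs of a treated and a control array ran from -0.024 to 0.118, and without fb-PMT replicate 2 the mean turned to -0.0069. The members with the largest differences were NDUFB1 (0.53, SE 0.19, adjusted p = 0.405) and NDUFS7 (0.47, adjusted p = 0.56), both of complex I. Leaving out 1 array moved NDUFB1 from 0.33 to 0.73 and NDUFS7, whose groups overlapped, from 0.18 to 0.75. The list's median of 0.0503 lay at the 96.5th percentile of 10000 random lists matched on mean level, whose 95th percentile was 0.0454. The array also holds 10 unnamed transcript clusters with identifiers that begin with TC0M, presumably for the mitochondrial chromosome. Their log2 differences were -0.115 to 0.0911, 4 higher and 6 lower, with 0 at an unadjusted p under 0.05.

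Within that list the mean log2 difference was 0.060 for the 32 measured genes of complex I (adjusted p = 0.408) and 0.036 for the 12 of complexes II and III, whose median was -0.0065 (adjusted p = 0.693, with SDHC at 0.35 and SDHD at 0.22). The 11 genes of cytochrome c oxidase had a mean of 0.094 (adjusted p = 0.337), with COX5A at 0.22 and COX6C at 0.21. The 16 genes of ATP synthase had a mean of -0.0038 and a median of 0.0066 (adjusted p = 0.963), with ATP5F1D at -0.44 and ATP5F1C at 0.16. Respiratory chain assembly factors had a mean of -0.046 over 39 genes (adjusted p = 0.628, and -0.084 to -0.0081 when 1 array was left out), with NDUFAF4 at -0.54 and NUBPL below the negative controls.

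Genes of the mitochondrial ribosome were lower in 59 of 77 cases, by a mean of -0.097, which missed the threshold (adjusted p = 0.0762). MRPS25 and MRPL38 had the largest differences, both -0.37. This list passed with an intensity trend (adjusted p = 0.0112) and without fb-PMT replicate 2 (mean -0.157, adjusted p = 0.00229), while without fb-PMT replicate 1 its mean was -0.037 (adjusted p = 0.706). The list had an adjusted p = 0.856 with an estimated correlation. Mitochondrial protein import had a mean of -0.054 over 30 genes (adjusted p = 0.52), with GRPEL2 at -0.40 and GFER below the negative controls. Mitochondrial biogenesis and dynamics had a mean of -0.103 over 30 genes (adjusted p = 0.33). POLRMT, the mitochondrial RNA polymerase (-0.80, -1.15 to -0.46 when 1 array was left out, adjusted p = 0.392), and PPRC1, a coactivator of the PGC-1 family (-0.57, adjusted p = 0.346), had the largest differences there. In each of these lists 0 members passed over all genes or adjusted over the list alone.

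In central metabolism, PFKFB3, which makes the glycolytic activator fructose 2,6-bisphosphate, was 2.1-fold higher (adjusted p = 0.115) and was the 1 member of the 21 measured glycolysis genes that rose when adjusted over the list alone. The list's mean was 0.097 (adjusted p = 0.314), and HK2 was below the negative controls. The tricarboxylic acid cycle list had a mean of 0.060 over 26 genes (adjusted p = 0.52, and 0.010 to 0.109 when 1 array was left out). Its largest differences were those of PCK2, below the negative controls, and SDHC. Fatty acid oxidation had a mean of 0.097 over 24 genes (adjusted p = 0.227), with ETFDH at 0.78 and ACADL below the negative controls. Cholesterol synthesis had a mean of 0.063 (adjusted p = 0.434, SREBF2 0.49 and HSD17B7 0.45), and fatty acid synthesis 0.039 (adjusted p = 0.806, ELOVL6 0.50, and ACACB below the negative controls).

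Genes of the type I interferon response rose as a group (camera adjusted p = 3.86e-15, and adjusted p = 0.559 with an estimated correlation). Of 35 measured members, 33 were higher and 25 had both fb-PMT arrays above both control arrays, with a mean log2 difference of 0.58. None passed over all transcript clusters, while 17 rose when adjusted over the list alone. With an intensity trend 9 rose over all transcript clusters, and 7 with the filter on negative controls. MX1, an antiviral GTPase, was 3.02-fold higher (adjusted p = 0.0556) and IFIT3, which belongs to the interferon-induced tetratricopeptide proteins, 2.95-fold higher (adjusted p = 0.0506). The 4 array pairs gave means of 0.545 to 0.608.

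Lysosomal genes, targets of the transcription factor TFEB, rose as a group by a mean of 0.26, with 29 of 34 higher (camera adjusted p = 2.28e-05, and adjusted p = 0.559 with an estimated correlation). None passed over all genes and 2 rose when adjusted over the list alone: ATP6V1A, a subunit of the lysosomal proton pump (1.86-fold, adjusted p = 0.246), and the autophagy protein gene WIPI1 (1.8-fold, adjusted p = 0.228). With an intensity trend 7 members rose over all transcript clusters, and 3 with the filter on negative controls.

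Ribosome biogenesis genes fell as a group by a mean of -0.24, with 28 of 32 lower (camera adjusted p = 4.45e-05, and adjusted p = 0.559 with an estimated correlation). The largest differences were those of PNO1, an assembly factor of the small subunit (-0.75, adjusted p = 0.306), and NCL, which encodes nucleolin (-0.49, adjusted p = 0.39), and 0 members passed, also adjusted over the list alone. Structural genes of the cytosolic ribosome had a mean of -0.022 over 42 genes (adjusted p = 0.836), with RPS14 at 0.20 and RPS19 at -0.19. Heat shock genes fell as a group by a mean of -0.26, with 18 of 19 lower (camera adjusted p = 0.00103, and adjusted p = 0.763 with an estimated correlation). HSPA1A, an inducible chaperone of the HSP70 family, was at -0.83 (-1.15 to -0.50 when 1 array was left out, adjusted p = 0.368), and HSPB8 was below the negative controls. Of the heat shock list 0 members passed, also adjusted over the list alone. With an intensity trend 1 heat shock gene and 1 ribosome biogenesis gene fell over all transcript clusters, and 0 of either with the filter on negative controls. Without control replicate 2 the heat shock list's mean was -0.201 and its adjusted p 0.145.

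**Figure D2:**
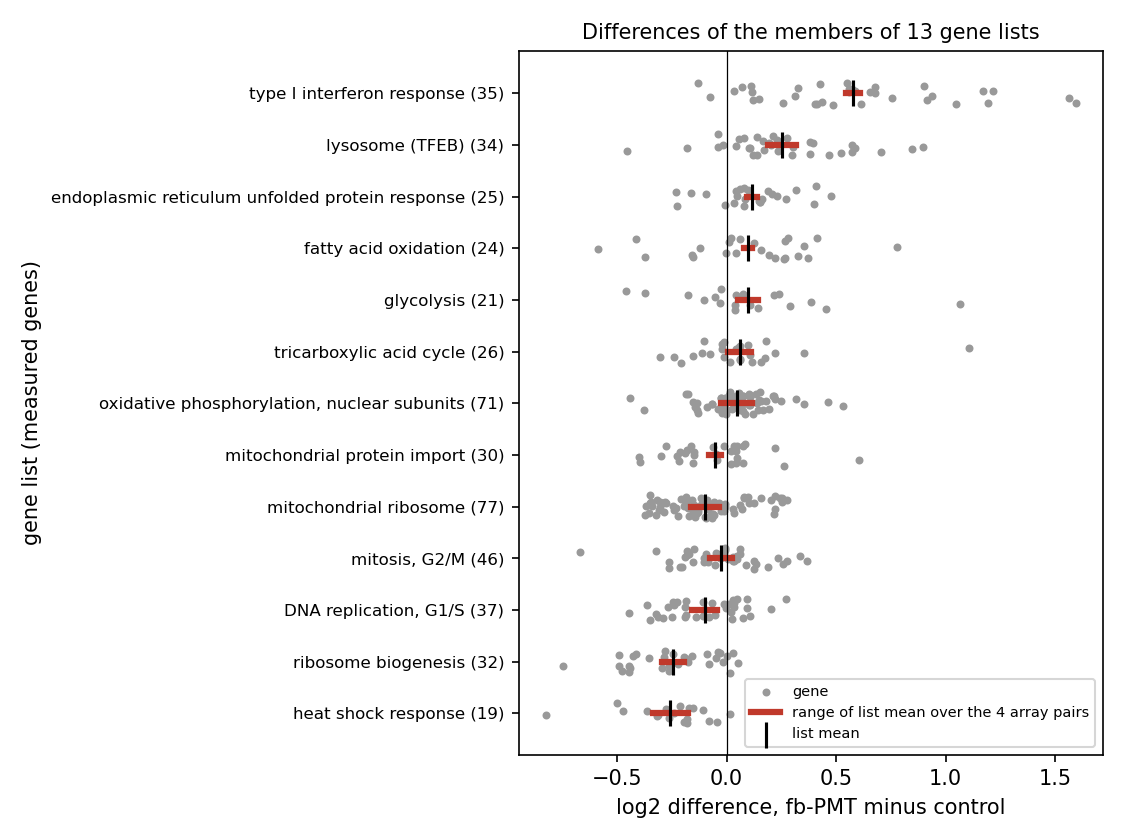
Log2 differences (fb-PMT minus control) of the measured genes of 13 gene lists, 1 grey point per gene, with the list mean (black tick) and its range over the 4 pairs of a treated and a control array (red bar). The interferon list lies to the right of 0 at 0.58, the oxidative phosphorylation list has a mean of 0.047 and a range that crosses 0, and the ribosome biogenesis and heat shock lists lie to the left at -0.24 and -0.26.

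Of the 39 lists tested, 4 passed camera with the preset correlation, 2 higher and 2 lower. None passed with an estimated correlation, and none by fry's directional test, whose adjusted p was 0.135 for the interferon, lysosome and ribosome biogenesis lists and 0.144 for the heat shock list. Fry's mixed test, which takes changes of members in either direction, passed 25 lists. These included complexes II and III (adjusted p = 0.0156), the tricarboxylic acid cycle (0.0053), glycolysis (0.0053), the mitochondrial ribosome (0.0489) and fatty acid oxidation (0.0498). Complex I (0.304), cytochrome c oxidase (0.64), ATP synthase (0.623) and the oxidative phosphorylation list (0.238) did not pass it. Passing the mixed test does not show that single members changed. In complexes II and III and in the mitochondrial ribosome, 0 members had an unadjusted p under 0.05 in limma's test. The tricarboxylic acid cycle had 1 such member, and glycolysis and fatty acid oxidation 2 each, all higher.

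Among cell cycle genes, the DNA replication list had a mean of -0.10 over 37 genes (adjusted p = 0.181, TIPIN -0.45 and CHAF1B -0.37). The mitosis list had a mean of -0.027 over 46 genes (adjusted p = 0.834), with the kinesin gene CENPE at -0.67 and the phosphatase gene CDC25C at 0.37. Replication-dependent histone genes had a mean of -0.0084 over 44 genes (adjusted p = 0.987), with H4C1 at 0.54 and H2BC17 below the negative controls. The p53 target list had a mean of 0.041 (adjusted p = 0.596, AEN -0.77 and GDF15 0.73) and the apoptosis list 0.092 (adjusted p = 0.239, BAK1 0.79 and CASP2 -0.50). No member of these lists passed, over all genes or adjusted over the list alone. With an intensity trend, over all transcript clusters, 1 mitosis gene fell, and 1 gene rose and 1 fell in each of the p53 and apoptosis lists.

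Among stress pathways, the unfolded protein response list was higher in 20 of 25 genes by a mean of 0.116 and missed the threshold (adjusted p = 0.0762, and 0.0112 with an intensity trend), with SEC24D at 0.48 and TXNDC5 at 0.41. The ATF4 list had a mean of 0.031 over 39 genes (adjusted p = 0.836). Adjusted over the list alone, 2 of its genes rose: the folate enzyme gene MTHFD2 (2.22-fold, adjusted p = 0.0909) and, named after its value was seen, NUPR1 (2.09-fold, adjusted p = 0.126). PCK2 had the other of its largest differences. The NRF2 target list had a mean of 0.088 over 26 genes (adjusted p = 0.337), and adjusted over the list alone 1 gene rose, the glutathione peroxidase GPX2 (at least 2.85-fold higher, adjusted p = 0.0577), and 1 fell, AKR1B10. With an intensity trend 5 NRF2 targets rose and 1 fell over all transcript clusters, and with the filter on negative controls 1 rose and 1 fell. The hypoxia list had a mean of -0.011 and a median of 0.072 over 30 genes (adjusted p = 0.963). PFKFB3 was the 1 member to rise over the list alone, and EGLN3 was below the negative controls. Metallothioneins had a mean of 0.134 over 11 genes (adjusted p = 0.227, MT1F 0.48 and MT1E 0.45).

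The NF-kB and cytokine list had a mean of 0.20 over 23 genes (adjusted p = 0.227), of which 12 were below the negative controls on all 4 arrays. IRF1 was its 1 member past the threshold over all genes. Adjusted over the list alone 2 rose and 2 fell. Besides IRF1, and named after their values were seen, these were TNFAIP2 (2.11-fold higher) and CXCL1 and TRAF1, both below the negative controls. The stemness list had a mean of 0.146 and a median of 0.039 over 20 genes (adjusted p = 0.693), with 11 higher and 9 lower. ABCG2 was its 1 member past the threshold, and its difference of 3.49 weighs heavily in that mean. Of the 20 genes, 9 were below the negative controls on all 4 arrays. Adjusted over the list alone 3 rose and 2 fell. Besides ABCG2, and named after their values were seen, ALDH1A3 was at 0.91 and CD24 at 0.53, while SOX2 and DCLK1, the falls, were below the negative controls. Immediate early genes had a mean of 0.024 and a median of -0.059 over 34 genes (adjusted p = 0.987), with EGR1 at 0.99 and JUND below the negative controls on both control arrays, where its groups overlapped. Mesenchymal and matrix genes had a mean of -0.045 over 30 genes (adjusted p = 0.628), with MMP14 at 0.60 and TWIST1 below the negative controls.

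The drug's reported target was examined through its subunits. ITGAV, which encodes integrin αv, went from a log2 value of 11.78 to 12.21 (difference 0.43, SE 0.15, adjusted p = 0.405), whereas ITGB3, the β3 subunit, was below the negative controls in both groups (4.87 and 4.54). The nuclear thyroid hormone receptor genes THRA and THRB differed by -0.078 (adjusted p = 0.891) and 0.098 (adjusted p = 0.876). The integrin and thyroid hormone receptor list had a mean of -0.015 over 23 genes (adjusted p = 0.967). KLF9, a thyroid hormone target, was the 1 member to rise over the list alone, although it was below the negative controls in both groups, and ITGB4 was at -0.45. Angiogenesis genes were lower in 15 of 21 cases with a mean of -0.159 (adjusted p = 0.147), and 0 passed, also over the list alone. Of these 21 genes, 13 were below the negative controls on all arrays, so the count and the mean rest largely on background values. VEGFA was at -0.57 (adjusted p = 0.35) and EPHA2 at -0.46 (adjusted p = 0.392).

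Epithelial markers were far above the negative controls in both groups, with control and treated log2 values as follows: KRT8 16.44 and 16.15, KRT18 15.73 and 15.27, KRT19 15.32 and 15.13. EPCAM, an epithelial adhesion molecule, was at 15.18 and 15.53. None of these differences passed. The glial markers GFAP (4.29 and 4.13) and OLIG2 (2.63 and 2.78), the fibroblast marker COL1A1 (4.42 and 4.14) and the leukocyte marker PTPRC (3.81 and 3.43) were below the negative controls in both groups, as were all 19 measured genes of the glial and glioblastoma list on all 4 arrays. Of the pancreatic ductal and epithelial list, 7 of 21 were below the negative controls on all arrays. That list had a mean of 0.013 (adjusted p = 0.963), and adjusted over the list alone 4 rose and 3 fell. The rises were TSPAN8 (2.08-fold, adjusted p = 0.123) and, named after their values were seen, ELF3 (0.83), LCN2 (0.63) and CFTR (0.62). The falls were KRT7 (1.93-fold lower, adjusted p = 0.192), CEACAM6 (-0.53) and PDX1, which was below the negative controls. The glial list had a mean of -0.132 (adjusted p = 0.259, with SOX2 and ALDH1L1 its largest differences), the fibroblast list -0.175 (adjusted p = 0.337, with FAP and PDGFRB) and the leukocyte list -0.057 (adjusted p = 0.836, with CSF1R and PTPRC), and all 6 of these genes were below the negative controls. On all 4 arrays 8 of the 10 measured fibroblast genes and 9 of the 11 leukocyte genes were below them.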

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

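The counts of calls depended on the variance model and on which transcript clusters were tested. The 21 calls are all among the 403 made with an intensity trend (293 higher, 110 lower) and the 394 with a robust trend (286 and 108). Leaving out the lowest 30% gave 61 higher and 6 lower, and testing only transcript clusters with 1 symbol 42 higher and 2 lower. The filter on the negative controls, added after the data were seen, gave 216 higher and 73 lower, and an unadjusted p under 0.05 with at least 2-fold gave 148 and 40. Fewer tests and another spread estimate come with these filters; the cause was not tested further. Leaving out 1 array at a time gave 1 to 9 calls higher and 0 lower, with the lone sample assumed to vary like the other group. The lists past the threshold were 7 with an intensity trend, 0 with an estimated correlation, 0 by fry's directional test and 25 by its mixed test. The mitochondrial ribosome list passed with an intensity trend (adjusted p = 0.0112), the lowest 30% left out (0.03), renewed quantile normalization (0.0056), the filter on negative controls (0.00529) and without fb-PMT replicate 2 (0.00229). The unfolded protein response (0.0112) and metallothionein (0.0115) lists passed with an intensity trend, DNA replication with renewed quantile normalization (0.0339), and the NF-kB list with the filter on negative controls (mean 0.464, 0.031). The robust trend has no counterpart for lists and was not run there. With the replicate number as a replicate block there was 1 call. Deviations of same-numbered arrays correlated at 0.042, over too few arrays to tell if numbers pair samples. The OXPHOS list's mean ran from -0.00685 to 0.101 when 1 array was left out.

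Values that crossed 0 belonged to results that did not pass, and the cause was not tested. With the lowest 30% left out, the integrin list was at 0.00381, histones at 0.00828 and the pancreatic list at -0.00109. With the filter on negative controls, hypoxia was at 0.0316 and immediate early genes at -0.0291. Leaving out 1 array gave -0.51 to 0.19 for GFAP, -0.15 to 0.43 for OLIG2 and -0.066 to 0.26 for THRB. Among lists the same ranges were -0.0303 to 0.00809 for hypoxia, -0.127 to 0.0134 for leukocytes, -0.0327 to 0.025 for ATP synthase and -0.0707 to 0.0178 for mitosis. They were -0.0149 to 0.141 for cholesterol synthesis, -0.0721 to 0.0553 for histones and -0.0648 to 0.0209 for the cytosolic ribosome. For complex I they were -0.0148 to 0.135, for complexes II and III -0.0078 to 0.0793, and for the pancreatic list -0.0408 to 0.0673. Without crossing 0, the range was also wide for cytochrome c oxidase (0.0548 to 0.134), DNA replication (-0.138 to -0.0631), p53 targets (0.00199 to 0.0797) and NRF2 targets (0.046 to 0.131). It was also wide for the fatty acid synthesis (0.0141 to 0.0629), immediate early (0.0106 to 0.0375), mesenchymal (-0.071 to -0.0196), integrin (-0.0296 to -0.000236), fibroblast (-0.277 to -0.0728) and glial (-0.205 to -0.0594) lists. Of 103 named genes, 31 moved by over 1.5 times when 1 array was left out, with 0 of them among the 12 largest rises or the 12 strongest falls. Among the 31, those above the negative controls and not given elsewhere were MMP14 (0.24 to 0.96), ATP5F1D (-0.68 to -0.21), GRPEL2 (-0.63 to -0.17), COX5A (0.11 to 0.33), COX6C (0.11 to 0.32), ETFDH (0.51 to 1.05), GDF15 (0.49 to 0.98), H4C1 (0.35 to 0.72), MT1F (0.31 to 0.65), RPS14 (0.10 to 0.30) and THRA (-0.15 to -0.0097). Over all comparisons of named genes with an alternative, 1158 kept their side of the threshold and direction, 102 newly passed, 47 no longer passed, and 4 changed sign, which are those of GFAP, OLIG2 and THRB above. Over all comparisons of the lists, the oxidative phosphorylation list aside, 532 kept both, 9 newly passed, 9 no longer passed, and the 17 sign changes are those above. The interferon, lysosome and ribosome biogenesis lists passed without each array in turn. Signal over background limits the dim genes: 11820 transcript clusters were below the negative controls on all 4 arrays.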

Other observations

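A list of antigen presentation, guanylate-binding protein and apolipoprotein L genes was written after 7 of its members had been seen among the strongest rises, so those 7 are not independent evidence. The list's theme was chosen from these data, so its other members describe the pattern and are no independent test of it either. None of the list is in the type I interferon list. Of its other 30 measured members, 27 were higher and 23 rose when adjusted over those 30 alone, though 0 passed over all genes. The 23 of them above the negative controls on any array were all higher, by 2.16-fold on average. Among them, named after their values were seen, were the immunoproteasome genes PSMB8 (2.44-fold) and PSMB10 (3.72-fold), the peptide loading gene TAPBPL (2.93-fold), GBP3 (2.89-fold) and the class II antigen genes HLA-DRA (2.43-fold) and HLA-DMA (2.49-fold). B2M, the light chain of class I antigens and likewise chosen, was 1.9-fold higher from a control log2 value of 15.36. The 4 array pairs gave mean log2 differences of 0.848 to 0.877 for these 30 genes. In limma's camera their adjusted p over 7 such lists was 2.8e-23, and adjusted p = 0.0521 with an estimated correlation. Neither value accounts for the choice of the theme from these data. Also named after their values were seen, the chemokine genes CXCL9, CXCL10 and CXCL11, IDO1 and the regulators CIITA and NLRC5 were below the negative controls on all arrays. HLA and GBP genes have close paralogs, so their individual values are uncertain.

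A list of epithelial junction genes was written after CLDN7 and JUP had been seen among the strongest rises. Without both, its 23 measured members had a mean of 0.103, with 13 higher, and the list did not pass (camera adjusted p = 0.27). Adjusted over those 23 alone, PKP2 (0.91) and ST14 (0.84) rose, named after their values were seen. Lists of retinoic acid, aryl hydrocarbon, PPAR and thyroid hormone receptor targets and of interferon ligands did not pass.

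The tests of sample splits, of fewer cycling cells and of single receptor targets were chosen after the results they bear on had been seen. The 4 arrays make 3 splits into 2 and 2, too few for a share under 0.05. Of these 1 split, the real one, gave 21 calls and the highest of the others 0.

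The higher type I interferon list was weighed first. Drift between arrays that depends on intensity is argued against, since the list's median of 0.558 lay above all 10000 random lists of matched level (5th to 95th percentile -0.0821 to 0.0949). An interferon made by the treated cells remains open: 0 of 20 measured interferon genes were above the negative controls and higher on both fb-PMT arrays. All 20 were below background, where a low transcript or an earlier pulse could not be seen. A response to fb-PMT, the difference the design names, may explain the list, and this hypothesis had no test beyond the comparison itself.

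The rises of ABCG2 and PLAAT4, known targets of ligand-activated transcription factors, raised the hypothesis that fb-PMT may act on such a receptor. Without the called genes, members above background had mean differences of 0.187 for retinoic acid receptor targets (95% interval -0.365 to 0.74), 0.0642 for aryl hydrocarbon receptor targets, 0.0761 for PPAR targets and 0.00683 for thyroid hormone receptor targets. With members below background kept in, the means were 0.0876, -0.0794, -0.192 and 0.0942 in the same order. None of the lists passed camera. Called genes included, 8 retinoic acid targets were higher and 13 lower, and 10 PPAR targets were higher and 10 lower. For aryl hydrocarbon targets 5 were higher and 6 lower, and for thyroid hormone targets 9 and 8. Single members higher at an unadjusted p under 0.05 were counted, and falls were not. They were more than in matched random lists for retinoic acid targets (5 of 20, permutation p adjusted over 4 lists 0.011) and thyroid hormone targets (4 of 17, 0.03). For aryl hydrocarbon (0.57) and PPAR targets (0.69) they were not. Named after their values were seen, of the 5 RARB, RARRES1 and CYP26A1 were below the negative controls on all arrays. The other 2 of the 5, RARG and TNFAIP2, were above them on both fb-PMT arrays, and TNFAIP2 is also in the NF-kB list. The 4 thyroid hormone targets, HR, KLF9, ADSS1 and FURIN, were below them on all arrays. A condition that at least 50% of such members lie above background was therefore added after the counts were seen. In this count of single members both receptors are left open because of that condition, without which their targets would have counted in favour. The tests of the lists as groups decided for none of the 4 receptors and excluded none. The thyroid hormone list holds neither ABCG2 nor PLAAT4.

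The lower ribosome biogenesis list was weighed last. Intensity-dependent drift is argued against by its median of -0.254, below all 10000 matched random lists (5th to 95th percentile -0.0625 to 0.0802). Fewer cycling cells remain open: against a bound of -0.122, 50% of the list's fall and set after the results were seen, the mitosis list's mean was -0.0265 (SD between replicates 0.0449), but that of the DNA replication list was -0.10 (SD 0.0428). Less MYC transcript, a known driver of these genes, remains a candidate explanation: MYC differed by -0.328 (95% interval -0.685 to 0.0286), which holds both no change and a fall of the size of the list's.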
